A study of Triticum aestivum with 12 samples.

How the data were processed

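Expression was measured on 12 Affymetrix wheat genome arrays, 3 for each of 4 combinations of growth temperature and CO2, from RNA of pooled leaves labelled with a 3' in vitro transcription kit, per the labels. The deposited values are log2 intensities that the authors made with RMA (background correction, normalisation across arrays and median polish), per the submitters' processing notes, which state neither software nor version. The log base was read from the values: the highest is 13.2965, above what natural logs of a 16-bit scanner can reach, and negative values (lowest -0.70) exclude a linear scale. The values lie lower than RMA usually gives, so an offset or another background step is possible, and differences between groups rather than levels carry the comparisons. No value was missing. The pots of each condition were spread over growth chambers, per the labels, but no chamber is given per array, so chambers could not be separated from groups.

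Of 61290 probe sets, 111 AFFX controls were left out, and all 61179 others were tested without a filter on level. Gene symbols came from the array annotation, looked up in a reference gene table for wheat. There were 1273 probe sets with 1 symbol, 0 with several and 59906 with none. The symbols named 771 genes, of which 770 matched the reference table, and 102 had a readable symbol or synonym. The reference table's coordinates were not used here, since the array names no genome build.

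Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 12 arrays, sharing 1 estimate of spread per probe set. The 6 contrasts were elevated minus ambient CO2 in non-acclimated and in cold-acclimated leaves, the difference and the mean of these effects, and cold-acclimated minus non-acclimated at each CO2 level. Tests were two-sided, adjusted by Benjamini-Hochberg over 61179 probe sets, and called at an adjusted p of 0.05, with a subset at 2-fold or more counted besides. Rose, fell and called refer to this threshold. These tests rest on 3 replicates per group, and p-values describe this one growth experiment. The CO2 effect in non-acclimated leaves and the cold effect at ambient CO2 share the NAAC arrays, so their calls were not compared.

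Genes were named by a rule fixed before the data were examined. In each comparison of groups and in the average CO2 effect, these were the 12 largest rises and 12 largest falls among genes with 1 symbol, an adjusted p under 0.05, a change of at least 2-fold and no overlap between the groups' arrays. For the difference of the CO2 effects the 6 largest each way were named, without the overlap rule. In each comparison the probe set with the smallest adjusted p stood for a gene, and up to 4 members of each gene list were added. Values of a gene can thus come from different probe sets in different comparisons, as for LOC543233, LOC542989, LOC100037609 and LOC100037634. Genes outside this rule are marked in the text as chosen after their values were seen.

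The 24 gene lists were patterns fixed before the data were examined and matched to symbols and synonyms. Of these, 12 matched no gene and 11 matched 1 or 2 genes, for which calls were counted but no set test was run. Set tests used limma's camera with a preset correlation of 0.01 on 1 probe set per gene, the brightest, with all named genes as background. Camera with an estimated correlation was run beside it, as was fry, a directional test that does not compare a list with other genes and from which no call was taken. A list needed 3 genes to be tested, which only the protease and xylanase inhibitor list and the union of the biotic stress lists had. Correlations of effects across probe sets are descriptive. Single measures of array quality were compared by exact permutation tests.

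The alternatives fixed beforehand were quantile normalisation repeated on the deposited values, median centring, leaving out probe sets under the 40th percentile of mean level, leaving out cross-hybridising probe sets, fits on 6 arrays, a trended robust prior, array weights, a replicate block, thresholds with a 2-fold minimum, and leaving out each array. Cyclic loess and rescaling by the bacterial spike-in controls were added after seeing the data. The pipeline was tested on simulated data with 200 changed probe sets per comparison among 61179. For log2 changes of 0.5, 1 and 2, it recovered 20.9%, 88.1% and 100% for CO2 in non-acclimated leaves, and 25.4%, 85.1% and 100% in cold-acclimated leaves. It recovered 2.99%, 52.2% and 97.0% for the difference, and 74.6%, 100% and 100% for the average. For cold it recovered 25.4%, 95.5% and 100% at ambient CO2, and 17.9%, 89.6% and 100% at elevated CO2. Fewer probe sets were changed than were called in the data (3606 to 18016), which makes the adjusted threshold stricter. On this count the shares may understate recovery in the data. The simulated noise was normal and independent between probe sets, without shifts of whole arrays, which may overstate it. False calls ran from 2 to 11 per comparison. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.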

Results

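Gene expression was measured in fully expanded leaves (leaf 3) of the winter wheat cultivar Norstar on 12 Affymetrix wheat genome arrays. Plants grew from sowing either at 20 °C by day and 16 °C by night (non-acclimated) or at a constant 5 °C (cold-acclimated). Each temperature was combined with ambient CO2 (380 µmol per mol) or elevated CO2 (700 µmol per mol). The 4 groups are called NAAC (non-acclimated, ambient CO2), NAEC (non-acclimated, elevated CO2), CAAC (cold-acclimated, ambient CO2) and CAEC (cold-acclimated, elevated CO2). Each group had 3 biological replicates, each a pool of 3 leaves, and this number of arrays limits the precision. The file held 61290 probe sets, of which 61179 were tested after the array's control probe sets were set aside. A gene symbol was found for 1273 of the tested probe sets (771 genes), and 102 of these genes had a symbol or synonym other than a locus number. Every other gene below is given by its locus symbol, because the annotation paired it with no other name. Levels are deposited log2 values, changes are log2 differences with the standard error of the model, and SD is the spread of 3 arrays. Array medians lay near 0.6, so a level below about 1 is near the floor, and a fold to or from such a level is only a lower bound. The order of the largest changes is that of the measured values and stays open where such levels are involved.

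Every pair of arrays of the same group resembled each other more closely than any pair from different groups. Pearson's r across probe sets ran from 0.990 to 0.995 within groups and from 0.901 to 0.989 between groups, and no arrays held identical values. Signs of RNA and hybridisation quality moved with the groups. The 3' minus 5' difference of the ubiquitin controls was -0.80 ± 0.14 in NAAC, -0.89 ± 0.06 in NAEC, -1.28 ± 0.12 in CAAC and -1.25 ± 0.06 in CAEC (SD, n = 3). The 3' minus middle difference of the sucrose synthase controls was 3.59 ± 0.06 in NAAC and 3.17 ± 0.01 in NAEC without overlap, and 2.99 ± 0.10 in CAAC and 3.05 ± 0.09 in CAEC (SD, n = 3), so it moved with CO2 in non-acclimated leaves. The poly-A controls averaged 4.12 ± 0.20 in NAAC, 3.92 ± 0.09 in NAEC, 3.65 ± 0.09 in CAAC and 3.30 ± 0.17 in CAEC, so they were lower in the cold and, in cold-acclimated leaves, lower under elevated CO2. The 18S rRNA control stood at 8.98 ± 0.15, 8.71 ± 0.36, 9.62 ± 0.29 and 9.26 ± 0.13 in the same order. The slope of the bacterial spike-in controls was 1.01 ± 0.01 in NAAC, 0.930 ± 0.011 in NAEC, 1.02 ± 0.01 in CAAC and 1.04 ± 0.01 in CAEC (SD, n = 3). The bioB spike-in, the dimmest, was 0.35 higher in NAEC than in NAAC (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). Wheat probe sets at the level of bioB went the other way, with a median change of -0.20 over 2106 probe sets.

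**Figure D1:**
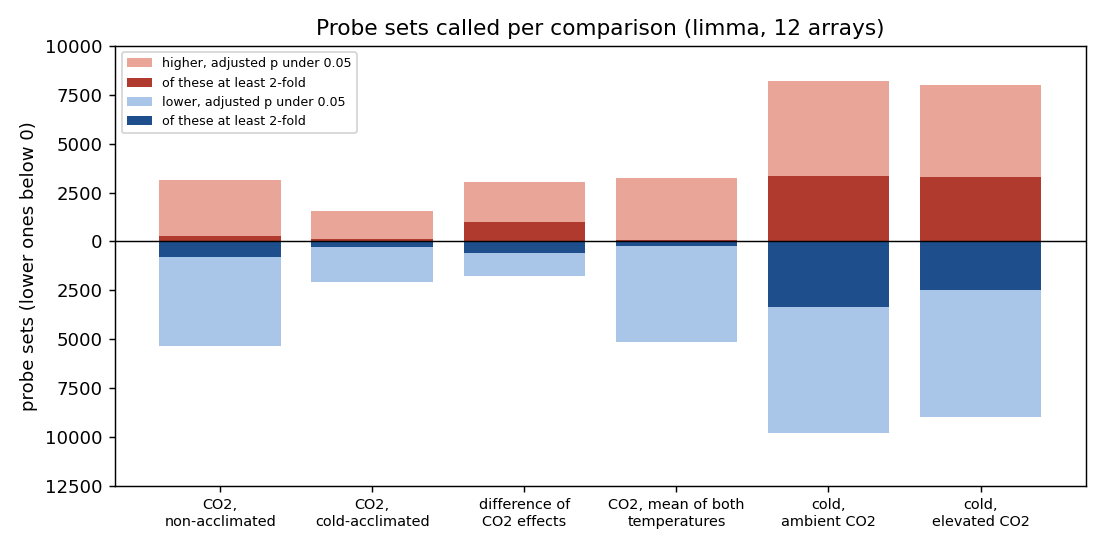
Number of probe sets called per comparison (vertical axis, those lower drawn below 0), with the probe sets changed at least 2-fold in the darker shade. The cold comparisons had 18016 and 17000 calls, against 8466 and 3606 for elevated CO2 in non-acclimated and cold-acclimated leaves.

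The first question was what elevated CO2 changed in leaves grown without cold, in particular among genes of biotic stress, which the study's title names. The pathogenesis-related gene PR5 (LOC543292) fell by 1.87 ± 0.18 (SE, n = 3 against 3; 3.65-fold, adjusted p = 4.10e-06), from 7.66 ± 0.46 in NAAC to 5.79 ± 0.28 in NAEC (SD). The xylanase inhibitor gene XIP-I (LOC542997) fell by 0.81 ± 0.10 (1.76-fold, adjusted p = 3.61e-05) on its brighter probe set and by 0.92 on the other. COMT1 (LOC543449), an O-methyltransferase gene by its symbol that is in no biotic stress list and was chosen after its values were seen, fell by 1.43 ± 0.13 (2.69-fold, adjusted p = 2.07e-06). The largest measured fall of a named gene was that of LOC543233, by 6.50 ± 0.21 (90.3-fold, adjusted p = 4.92e-11), from 7.90 ± 0.53 to 1.40 ± 0.37. Among the probe sets that stood for a gene here, the largest measured rise was that of LOC606346, by 2.87 ± 0.14 (7.29-fold, adjusted p = 1.95e-09), from 2.19 ± 0.23 to 5.06 ± 0.27. A probe set of LOC542989 that did not stand for its gene here had a larger rise, from 3.05 to 3.64 in the NAAC arrays to 6.27 to 6.62 in the NAEC arrays.

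Other steep falls in non-acclimated leaves were those of LOC543234 (fell by 5.06), LOC543363 (fell by 3.37), LOC543313 (fell by 2.96), LOC543197 (fell by 2.92) and LOC543201 (fell by 2.63). LOC543492 fell by 2.38, LOC542888 fell by 2.32, LOC100037560 fell by 2.16 and LOC542773 fell by 2.07. LOC543342 fell by 2.17 on its brighter probe set, while its other probe set, near 1.9 in NAAC, was not called (adjusted p = 0.0862). The fructan exohydrolase gene 6-FEH (LOC780575) fell by 2.13 ± 0.24 on one probe set and by 0.58 on another, and its remaining probe set was not called (adjusted p = 0.136). Rises followed in LOC542989 (2.73), LOC100125679 (2.55), LOC778406 (1.84), LOC543123 (1.76), LOC542817 (1.61) and LOC543086 (1.60). LOC542918 (1.25), LOC100037634 (1.19), LOC543145 (1.19), LOC100037633 (1.18) and LOC542946 (1.15) rose as well. Further probe sets of LOC100037560, LOC542888, LOC542817 and LOC542918 were not called. Under the rule for naming genes, which asks for a 2-fold change and no overlap between the groups, 19 named genes passed as higher and 44 as lower. Chance alone leaves 3 arrays against 3 without overlap in 10% of cases.

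In all, 8466 probe sets were called in non-acclimated leaves (13.8% of those tested), of which 3122 rose and 5344 fell. Among those changed at least 2-fold, 260 rose and 805 fell. The share of rises was 36.9% on the deposited values, 49.2% (3759 of 7636) after quantile normalisation was repeated, and 23.3% (2106 of 9039) with each array centred on its median. It was 8.04% (365 of 4538) after rescaling by the spike-in controls within their range of levels, where it was 24.9% as deposited, and 1.02% where the same line was extended to every probe set. Falls outnumbered rises among changes of 2-fold or more under each of these scalings, with 648 falls and 386 rises at the closest.

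Among 8 genes of the combined biotic stress list, fixed before the data were examined, 2 rose and 2 fell in non-acclimated leaves, and the counts adjusted over the list alone were also 2 and 2. PR5 and XIP-I fell, whereas PER1 (LOC543108) rose by 0.50 ± 0.13 and Prx1 (LOC606328) by 0.36 ± 0.10. PER1 went from 0.37 ± 0.10 to 0.87 ± 0.14, near the floor, so its rise carries little weight. Both rises were seen on the brightest probe set alone, and the other probe sets of PER1 (1) and Prx1 (3) were not called. The PER1 call was lost without NAAC replicate 1 (adjusted p = 0.0577) or NAEC replicate 3 (0.0610). The Prx1 call was lost with arrays centred on their medians (0.0755), after rescaling by the spike-in controls (0.0603), and without NAAC replicate 1 (0.0564), 2 (0.0652) or 3 (0.0896) or NAEC replicate 1 (0.0953). No shift of the whole list against the other named genes was found (camera p = 0.823, and 0.837 with an estimated correlation), and its mean (-0.21) differed in sign from its median (0.03) and from the direction of the test (up). Most of the list was near the floor (the serpins, a thionin gene and PER1), so these tests say little about biotic stress genes as a class in any comparison. The protease and xylanase inhibitor list of 4 genes was not called (adjusted p = 0.687), with mean -0.17 and median 0.01. Its 3 serpin genes lay within 0.4 of 0 in every group, so that XIP-I was its 1 fall, and also its 1 fall adjusted over the list alone.

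Of the other lists, the PR protein list (PR5 and a thionin gene near 0) had 1 fall and the peroxidase list (PER1 and Prx1) 2 rises, with the same counts adjusted over the list alone. The fructan list had 1 fall (6-FEH) and the lipid transfer list 1 rise (LTP3, LOC543095, by 0.49 ± 0.12), also 1 each adjusted over the list alone. The LTP3 call was lost without NAAC replicate 1 (adjusted p = 0.0627) or 3 (0.0590) or NAEC replicate 3 (0.0504). Of the 24 lists 12 matched no gene, among them those of resistance and defence signalling, phenylpropanoids, jasmonate, CBF and DREB factors and vernalization. No member was called, and none adjusted over the list alone, in the cold-regulated and LEA, photosystem, Rubisco, heat shock, ribosomal, seed storage or root and pollen lists. A second PsbP probe set (LOC543290), dimmer than the one the list used, rose by 0.70 (adjusted p = 0.000632). Chosen after their values were seen, GLU1A (LOC780595) fell by 2.04 ± 0.21 and the β-tubulin gene tubb1 (LOC543257) by 1.14 ± 0.12, whereas tubb2 (LOC543258) rose by 0.81 ± 0.14 and Hmgb3 (LOC543333) by 0.71 ± 0.10. CAT1 fell by 0.39 ± 0.09, GAPN by 0.46 ± 0.11 and cys1 (LOC543181) by 0.43 ± 0.09.

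**Figure D2:**
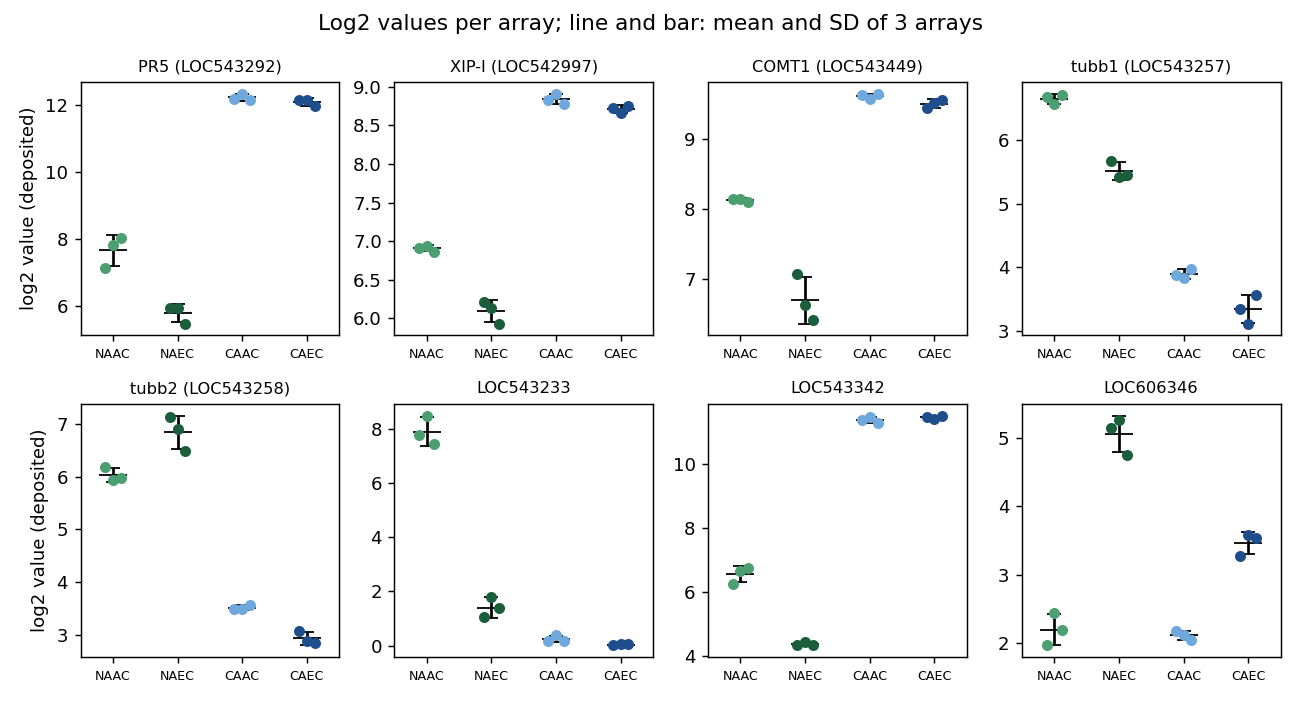
Deposited log2 values (vertical axis) of 8 genes in the 4 groups (horizontal axis), each point an array, with mean and SD of 3 arrays as line and bar. PR5 fell from 7.66 in NAAC to 5.79 in NAEC and stood at 12.24 in CAAC and 12.10 in CAEC.

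The same question was asked of cold-acclimated leaves. PR5 (LOC543292) was not called there, with a change of -0.14 ± 0.18 (SE, n = 3 against 3; adjusted p = 0.793) between 12.24 ± 0.10 and 12.10 ± 0.12 (SD). XIP-I (LOC542997) was not called either (-0.13 ± 0.10, adjusted p = 0.582), nor was COMT1 (LOC543449; -0.11 ± 0.13, adjusted p = 0.760), chosen after its values were seen. LOC543248 had the largest measured fall among named genes, by 2.51 ± 0.11 (5.70-fold, adjusted p = 6.76e-09), from 6.72 ± 0.03 to 4.21 ± 0.10. LOC543104 had the largest measured rise, from near the floor, by 2.34 ± 0.16 (5.06-fold, adjusted p = 6.29e-07), from 0.84 ± 0.35 to 3.18 ± 0.28.

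LOC543086 (1.95), LOC543499 (1.38), LOC606346 (1.35), LOC780678 (1.24) and LOC778400 (1.03) also rose in cold-acclimated leaves. LOC543201 and LOC100125738 each fell by 1.64, LOC100037518 fell by 1.38, LOC542830 fell by 1.26, LOC542947 fell by 1.05 and LOC543498 fell by 1.03. Further probe sets of LOC542830 and LOC543498 were not called. These were all the named genes that passed the naming rule here, 6 higher and 7 lower. Called were 3606 probe sets (5.89%), of which 1554 rose and 2052 fell, with 120 rises and 272 falls of at least 2-fold. Single arrays moved this count by more than 1.5 times. It was 2359 without CAAC replicate 1, 2230 without CAAC replicate 2, 2339 without CAEC replicate 1, 2120 without CAEC replicate 2 and 2140 without CAEC replicate 3. The share of rises was 43.1% as deposited, 53.7% (1830 of 3408) after repeated quantile normalisation, 34.6% (1260 of 3637) with arrays centred on their medians, 75.1% (1521 of 2025) after spike-in rescaling within the range of the controls, and 78.7% where that line was extended to every probe set. Rescaling within that range also reversed the balance of changes of at least 2-fold, to 50 rises and 32 falls, from 37 rises and 52 falls as deposited in that range.

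No gene of the combined biotic stress list was called in cold-acclimated leaves, with limma's adjusted p or adjusted over the list alone, and no shift of the list was found (camera p = 0.421, and 0.465 with an estimated correlation). With most members near the floor this rests mainly on PR5, XIP-I and Prx1. The protease and xylanase inhibitor list was not called (adjusted p = 0.427). The ribosomal list had 1 fall, and 1 rise and 1 fall adjusted over the list alone. Its fall was RPS29 (LOC606342), by 0.63 ± 0.14 (adjusted p = 0.0147), a call lost without CAAC replicate 1 (0.0525) or 3 (0.0578) or CAEC replicate 3 (0.0797). The fructan list had 1 rise, also 1 adjusted over the list alone, in the 6-FEH probe set (LOC780575) that rose by 0.53 ± 0.15. That call was lost when arrays were centred on their medians (0.0701), with cyclic loess (0.0807), with a replicate block (0.0675), without any 1 of the 6 cold-acclimated arrays (0.0548 to 0.199), and without NAAC replicate 2 (0.0522). Chosen after the values were seen, tubb1 (LOC543257) fell by 0.56 ± 0.12 (adjusted p = 0.0643 without CAEC replicate 2), and Hmgb3 (LOC543333) rose by 0.45 ± 0.10.

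Whether the CO2 effect depended on growth temperature was tested directly, as the effect in cold-acclimated leaves minus that in non-acclimated leaves. The CO2 effects on PR5 (LOC543292) differed by 1.73 ± 0.26 (SE, 3 arrays in each of 4 groups; adjusted p = 0.000484), on COMT1 (LOC543449) by 1.32 ± 0.19 (adjusted p = 0.000286) and on XIP-I (LOC542997) by 0.69 ± 0.14 (adjusted p = 0.00552). Each of these genes fell under elevated CO2 in non-acclimated leaves and was not called in cold-acclimated leaves. PR5 stood at 11.97 to 12.35 in the cold-acclimated arrays, above the brightest spike-in control (11.74). Its response at that level could not be checked against a control. The β-tubulin gene tubb2 (LOC543258) rose by 0.81 in the first and fell by 0.58 in the second, a difference of -1.39 ± 0.20 (adjusted p = 0.000276). COMT1 and tubb2 were chosen after their values were seen. The fall of tubb2 in cold-acclimated leaves was no longer called after spike-in rescaling (adjusted p = 0.0571) or without CAAC replicate 1 (0.0536), 2 (0.0559) or 3 (0.0619) or CAEC replicate 2 (0.0811) or 3 (0.0848).

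The largest positive differences were those of LOC543233 (6.29 ± 0.30), LOC543234 (5.06 ± 0.44), LOC543363 (3.27 ± 0.19), LOC543313 (3.02 ± 0.26), LOC543492 (2.82 ± 0.23) and LOC542888 (2.62 ± 0.26). All 6 fell in non-acclimated leaves. The first 3 of them were already below 1 in CAAC, so that little room was left for a fall in the cold, whereas LOC543313 stood at 6.64 in CAAC and 6.69 in CAEC, and LOC543492 at 8.78 and 9.22. Further probe sets of LOC542888 and LOC542817 had no called difference. The largest negative differences were those of LOC542989 (-2.35 ± 0.27), LOC543123 (-2.24 ± 0.17), LOC100037518 (-2.21 ± 0.24), LOC778406 (-2.17 ± 0.28), LOC100125679 (-2.13 ± 0.15) and LOC542817 (-1.94 ± 0.26). That of LOC542989 came from another probe set than the one that stood for it in non-acclimated leaves and in the average below. The CO2 effect differed for 4764 probe sets, 3016 with a positive and 1748 with a negative difference, and for 1556 the difference was at least 2-fold (985 positive, 571 negative). The positive share was 63.3% as deposited, 56.6% (2560 of 4524) after repeated quantile normalisation, 54.0% (2415 of 4470) after cyclic loess, 93.6% (4082 of 4359) after spike-in rescaling within the range of the controls, where it was 69.2% as deposited, and 99.2% where that line was extended to every probe set. Of the named genes, 46 had a positive and 21 a negative difference of at least 2-fold.

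In the combined biotic stress list 2 genes (PR5 and XIP-I) had a positive difference and none a negative one, against 2 and 2 adjusted over the list alone. No shift of the list was found (camera p = 0.673, and 0.698 with an estimated correlation), and its mean (0.13) differed in sign from its median (-0.17) and from the direction of the test (down). The protease and xylanase inhibitor list was not called (adjusted p = 0.909). CAT1 (0.66 ± 0.13), GAPN (0.63 ± 0.15) and GLU1A (LOC780595; 1.52 ± 0.30), chosen after their values were seen, had positive differences, and 6-FEH (LOC780575) differed by 1.10 ± 0.21. Across all probe sets the CO2 effects at the 2 temperatures, which share no arrays, correlated with Pearson's r = 0.173 and Spearman's rho = 0.182. Probe sets are not independent replicates, and r stayed between 0.146 and 0.201 with any 1 array left out. Both effects were called for 1325 probe sets: 267 rose in both (79.3 by chance), 601 fell in both (179 by chance) and 457 went opposite ways (240 by chance). These calls share 1 estimate of spread per probe set, and opposite changes exceeded chance too. Separate fits on 6 arrays each gave 213 (54.7 by chance), 539 (146 by chance) and 376 (180 by chance).

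**Figure D3:**
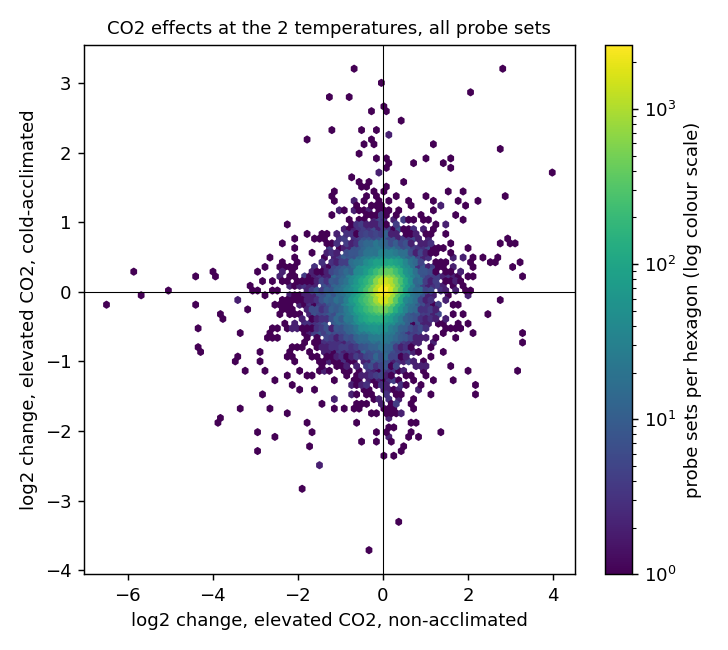
Log2 change under elevated CO2 in non-acclimated leaves (horizontal axis) against that in cold-acclimated leaves (vertical axis) for 61179 probe sets, shaded by the number of probe sets per hexagon on a log scale. The effects correlated with r = 0.173, and LOC543233 at -6.50 lies at the far left.

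The average of both CO2 effects asks what elevated CO2 changed whatever the temperature. LOC606346 rose by 2.11 ± 0.10 on average (SE, 6 arrays against 6; 4.31-fold, adjusted p = 2.70e-09) and was called in each temperature, although its effects differed. LOC543086 rose by 1.77 ± 0.11 (3.42-fold) and was also called in each. LOC543201 fell by 2.14 ± 0.09 (4.40-fold, adjusted p = 9.74e-10), LOC543248 fell by 2.01 ± 0.08 and LOC100125738 fell by 1.55 ± 0.11. The average fall of LOC543233, by 3.35 ± 0.15, came from non-acclimated leaves, since its effects differed by 6.29. PR5 (LOC543292) fell by 1.00 ± 0.13 on average and XIP-I (LOC542997) by 0.47 ± 0.07, both with a CO2 effect that differed between temperatures. Effects also differed for LOC542989, LOC100125679, LOC543201, LOC543248, LOC543197, GLU1A (LOC780595) and LOC542866, so their averages hold for neither temperature alone.

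LOC542989 (1.72 ± 0.12) and LOC100125679 (1.49 ± 0.07) completed the 4 named genes that rose under the naming rule. LOC543197 fell by 1.90 ± 0.10, GLU1A (LOC780595) fell by 1.28 ± 0.15, LOC542830 fell by 1.22 ± 0.08 and LOC542866 fell by 1.15 ± 0.10, which completed the 8 that fell. Called were 8416 probe sets, of which 3254 rose and 5162 fell, with 74 rises and 210 falls of at least 2-fold. The share of rises was 38.7% as deposited, 51.6% (3882 of 7517) after repeated quantile normalisation, 23.1% (2050 of 8862) with arrays centred on their medians, 16.5% (591 of 3582) after spike-in rescaling within the range of the controls, and 2.88% where that line was extended to every probe set. In the combined biotic stress list 2 genes fell and none rose, against 2 and 1 adjusted over the list alone, and no shift of the list was found (camera p = 0.749, and 0.768 with an estimated correlation). The protease and xylanase inhibitor list was not called (adjusted p = 0.429).

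What cold acclimation changed was asked at each CO2 level, first at ambient CO2. PR5 (LOC543292) rose by 4.58 ± 0.18 (SE, n = 3 against 3; adjusted p = 7.32e-12), from 7.66 ± 0.46 to 12.24 ± 0.10 (SD). XIP-I (LOC542997) rose by 1.93 ± 0.10 (adjusted p = 1.29e-10). LOC543287 had the largest measured rise among named genes, by 6.57 ± 0.18 (95.0-fold, adjusted p = 1.18e-13), though LOC543498 and LOC543438 rose from the floor. LOC543233 had the largest measured fall, by 8.05 ± 0.21 (at least 265-fold, adjusted p = 7.63e-14), from 8.18 ± 0.49 to 0.13 ± 0.42, on another probe set than the one given for CO2. LOC543363 fell by 7.17 ± 0.14 (at least 144-fold). Both ended at the floor, so their folds are lower bounds and their order is open. The methyltransferase gene PEAMT1 (LOC543067) fell by 3.42 ± 0.13 (10.7-fold), GLU1A (LOC780595) by 3.36 ± 0.21 and tubb1 (LOC543257) by 2.76 ± 0.12.

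LOC100125708 (6.13), LOC543330 (5.99), LOC543498 (5.88), LOC543317 (5.77), LOC606308 (5.43), LOC543453 (42.2-fold) and LOC543438 (5.26) followed among the rises in the cold at ambient CO2. LOC542839 (4.85), LOC543342 (4.83), LOC606391 (4.80) and LOC542790 (4.70) completed the 12 largest. Further probe sets of LOC543342 (adjusted p = 0.986), LOC543498 and LOC542936 were not called. Falls followed in LOC542812 (fell by 5.81), LOC543234 (fell by 5.29), LOC100037609 (fell by 5.11), LOC543150 (fell by 3.70), LOC543216 (fell by 3.69), LOC780692 (fell by 2.75) and LOC542936 (fell by 2.69). In all, 93 named genes passed the naming rule as higher and 120 as lower. Called were 18016 probe sets (29.4%), of which 8216 rose and 9800 fell, with 3364 rises and 3367 falls of at least 2-fold. The share of rises was 45.6% as deposited and 51.2% (9157 of 17890) after cyclic loess.

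Of the 8 genes of the combined biotic stress list 4 rose and none fell in the cold at ambient CO2, with the same counts adjusted over the list alone. These were PR5, XIP-I, Prx1 (0.55 ± 0.10) and PER1 (0.43 ± 0.13, near the floor), the last lost without NAAC replicate 1 (adjusted p = 0.0585) or CAAC replicate 2 (0.0938). The test of this list in the cold was not among those fixed beforehand. It gave camera p = 0.0329, which did not hold with an estimated correlation (p = 0.0763), after cyclic loess (0.0518), or without CAAC replicate 2 (0.0876), CAEC replicate 1 (0.0780) or 3 (0.0706) or NAEC replicate 3 (0.0788). The protease and xylanase inhibitor list was not called (adjusted p = 0.292), and 1 of its 4 genes rose. Both photosystem genes fell, PsbO (LOC543291) by 0.99 ± 0.10 and PsbP (LOC543290) by 0.94 ± 0.10. The fructan exohydrolase gene 1-FEH (LOC543441) fell by 1.36 ± 0.09 and LTP3 (LOC543095) fell by 2.33 ± 0.12. Both ribosomal genes rose, RPS29 (LOC606342) by 2.62 ± 0.14 and RPL9 (LOC543077) by 0.38 ± 0.13. The RPL9 call was lost after repeated quantile normalisation (adjusted p = 0.111), with only the 6 arrays compared (0.0577), and without NAAC replicate 1 (0.0993) or 3 (0.140) or CAAC replicate 2 (0.0502) or 3 (0.177). A dimmer RPS29 probe set went the other way, with a fall of 0.60. In these lists the counts adjusted over the list alone were the same, and the seed storage list had no call but 1 rise adjusted over the list alone. The cold-regulated and LEA genes COR410 and LEA1 (LOC543476) were not called and lay below 1 in every group. LEA1 was called as lower without NAAC replicate 2 (adjusted p = 0.0243).

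At elevated CO2 the cold raised PR5 (LOC543292) by 6.31 ± 0.18 (SE, n = 3 against 3; 79.4-fold, adjusted p = 1.80e-13) and XIP-I (LOC542997) by 2.62 ± 0.10 (adjusted p = 3.06e-12). COMT1 (LOC543449), chosen after its values were seen, rose by 2.81 ± 0.13, against 1.49 ± 0.13 at ambient CO2. The rise at elevated CO2 exceeded that at ambient CO2 by the same differences as tested above for the CO2 effects, 1.73 for PR5 and 1.32 for COMT1. LOC100125708 had the largest measured rise among named genes, by 7.33 ± 0.33 (160-fold, adjusted p = 2.36e-11), though LOC543287 rose from the floor, and LOC542812 had the largest measured fall, by 6.59 ± 0.17 (at least 96.1-fold, adjusted p = 6.47e-14), to the floor (0.75 ± 0.19). The β-tubulin gene tubb2 (LOC543258) fell by 3.90 ± 0.14 (15.0-fold) and PEAMT1 (LOC543067) by 3.48 ± 0.13.

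LOC543492 (7.31), LOC543330 (7.25), LOC543342 (7.09), LOC543317 (128-fold), LOC543287 (6.95), LOC100037560 (6.50), LOC542839 (6.40), LOC542887 (6.34), LOC606308 (5.91) and LOC543453 (5.56) also rose in the cold at elevated CO2. LOC778406 fell by 4.65, LOC100037609 fell by 4.06, LOC543363 fell by 3.90, LOC543216 fell by 3.86, LOC780692 fell by 3.67 and LTP3 (LOC543095) fell by 2.99. LOC542947 fell by 2.81, LOC100037634 fell by 2.76 and LOC543329 fell by 2.43. A further probe set of LOC543342 was not called. The naming rule was passed by 104 named genes as higher and 99 as lower. Called were 17000 probe sets (27.8%), of which 8013 rose and 8987 fell, with 3285 rises and 2474 falls of at least 2-fold. The share of rises was 47.1% as deposited, 54.9% (9051 of 16483) with arrays centred on their medians, 52.0% (8612 of 16562) after cyclic loess, 72.6% (3481 of 4792) after spike-in rescaling within the range of the controls, where it was 52.7% as deposited, and 95.4% where that line was extended to every probe set.

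In the combined biotic stress list 2 genes (PR5 and XIP-I) rose and none fell, with the same counts adjusted over the list alone, and no shift of the list was found (camera p = 0.219, and 0.276 with an estimated correlation), although p was 0.0345 with all probe sets as background. The protease and xylanase inhibitor list was not called (adjusted p = 0.520), and its mean (0.59) differed in sign from its median (-0.02). PsbO (LOC543291) fell by 1.14 ± 0.10 and PsbP (LOC543290) by 0.94 ± 0.10, and RPS29 (LOC606342) rose by 2.08 ± 0.14. The other fructan, lipid transfer and ribosomal genes kept the directions they had at ambient CO2, except that 6-FEH (LOC780575) rose here by 0.84 ± 0.15 on its brightest probe set alone. A further Prx1 probe set (LOC606328) rose by 0.29, a call lost after repeated quantile normalisation (adjusted p = 0.251) and in many other settings, among them without CAEC replicate 1 (0.102) or 2 (0.162). A gliadin gene (LOC543211) rose by 0.38 ± 0.11, a call lost without CAEC replicate 1 (adjusted p = 0.0646). It lay near the floor, at 0.58 to 0.59 in NAEC and 0.91 to 1.04 in CAEC, so its rise carries little weight. In none of the 6 comparisons was the protease and xylanase inhibitor list called, with the preset or an estimated correlation. The combined list, tested by camera against the other named genes without adjustment, was under 0.05 only for cold at ambient CO2. With an estimated correlation it was not. Across probe sets the cold effects at the 2 CO2 levels, which share no arrays, correlated with Pearson's r = 0.876 (0.866 to 0.879 with any 1 array left out) and Spearman's rho = 0.645. Rises in both numbered 5902 (1076 by chance), falls in both 6129 (1440 by chance) and opposite changes 327 (2490 by chance). Separate fits on 6 arrays each gave 5802, 5913 and 296.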

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

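Of the tests in this part, those confined to the range of the spike-in controls were chosen only after the result was seen, and those with cyclic loess or the spike-in line on all probe sets use alternatives added after the data were seen.

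The CO2 effect differed between cold-acclimated and non-acclimated leaves for 4764 probe sets, 1556 of them by at least 2-fold, in a direct test of the difference. The named genes with the largest differences (cold-acclimated minus non-acclimated, log2) were LOC543233 (6.29), LOC543234 (5.06), LOC543363 (3.27), LOC543313 (3.02), LOC543492 (2.82) and LOC542888 (2.62). On the negative side they were LOC542989 (-2.35), LOC543123 (-2.24), LOC100037518 (-2.21), LOC778406 (-2.17), LOC100125679 (-2.13) and LOC542817 (-1.94). Of 100 splits of the arrays within each temperature, 2, counting the real one, gave at least the real 4764 calls. The other one swaps the CO2 labels in one temperature, which turns the difference into the average effect (8416), and the highest of the remaining splits gave 3340. At a share of 0.05 this excludes only chance with no CO2 effect at either temperature. On equal CO2 effects at both temperatures the splits decide nothing, because they shuffle the CO2 labels at both.

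The average CO2 effect had 8416 calls, and 1 of 100 splits, the real one, gave as many. The highest other gave 4764, by the same swap, and 3075 without it. Chance with no CO2 effect at either temperature can thus be excluded at a share of 0.05. For comparisons of 3 arrays with 3 there are only 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many calls. The real and highest other counts were 8466 and 0 for CO2 in non-acclimated leaves, 3606 and 0 in cold-acclimated leaves, 18016 and 0 for cold at ambient CO2 and 17000 and 0 at elevated CO2.

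Elevated CO2 had 2.35 times as many calls in non-acclimated as in cold-acclimated leaves (8466 and 3606). The NAEC arrays showed a compressed range of the spike-in controls, which could inflate the count in non-acclimated leaves. The ratio stayed at 2.067 after cyclic loess, the lower of this and the spike-in line on all probe sets. That line decides nothing, because it turned nearly all calls in non-acclimated leaves into falls (54440 of 55000). Cyclic loess alone argues against compression as the whole cause, as far as it removes compression. Spike-in rescaling within the range of the controls (2.241) decides nothing, because it moves most probe sets there the same way. The deposited values within that range gave a ratio of 1.36 (3456 and 2550) in a separate fit, adjusted over 5776 probe sets. Calls of the full fit were not counted inside and outside the range, so where the excess lay stays open. A single deviant array is argued against by a lowest ratio of 1.748 when each array was left out in turn, although the size of the ratio rests on single arrays (up to 3.81, without CAEC replicate 3). As a cause of this ratio, a dependence of the CO2 response on growth temperature stays open as a hypothesis. So do chambers and processing days, which the labels do not give per array.

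Falls of at least 2-fold outnumbered rises under elevated CO2 in non-acclimated leaves, 805 to 260. Compression of the NAEC arrays could produce falls among bright probe sets. The ratio of falls to rises was 3.10 as deposited and 2.136 after cyclic loess, the lower of this and the spike-in line on all probe sets. That line decides nothing, because it lowers nearly all probe sets (6974 falls and 98 rises of at least 2-fold). Cyclic loess alone argues against compression as the whole cause, as far as it removes compression. The size of the ratio depends on the scaling (1.68 after repeated quantile normalisation). The ratio of 17.15 after spike-in rescaling within the range of the controls decides nothing, because the line lowers most probe sets there. Differences in RNA quality or handling between groups stay open, since the labels give no dates and the 3' minus middle difference of the sucrose synthase controls was 3.59 in NAAC and 3.17 in NAEC.

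The control probe sets of wheat glucose-6-phosphate dehydrogenase, which no comparison in the report uses, were higher in the cold. Their mean over 3 probe sets rose in level from 2.13 to 4.63 at ambient CO2, a difference of 2.50, and from 1.92 to 4.32 at elevated CO2, a difference of 2.41. The 5' probe set stood at 0.59 in NAAC and 0.60 in NAEC, near the floor, so these mean differences are lower bounds. Each difference reached an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow, with all 3 cold arrays above all 3 others. No explanation was tested for this.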

How the results depend on the processing

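Cyclic loess and both uses of the spike-in controls were chosen only after the data were seen. All other alternatives were fixed before.

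Without cross-hybridising probe sets the counts were 5340 and 1991 for CO2 in non-acclimated and cold-acclimated leaves, 2771 for the difference of these effects, 5426 for their average, and 11656 and 10934 for cold at ambient and elevated CO2. Fewer probe sets were tested by construction. With a 2-fold minimum the counts in the same order were 1065, 392, 1556, 284, 6731 and 5759 (1074, 401, 1614, 284, 6735 and 5762 with unadjusted p), lower by construction. Among probe sets within the range of the spike-in controls (5776 of 61179), fewer by construction, deposited values gave 3456, 2905, 3338, 4837 and 4750, without the cold-acclimated CO2 count, which stayed within 1.5 times at 2550. Spike-in rescaling there gave 4538, 2025, 3582, 4638 and 4792. The difference had 4359, within 1.5 times of the full count but above the 2905 of the deposited values in that range. Extended to all probe sets the line was extrapolated for 90.5% of them and gave 55000 for CO2 in non-acclimated leaves, 54476 for the difference, 30414 for the average and 56696 for cold at elevated CO2. It also moved the median change of all probe sets, by -0.75, 0.93, -0.28 and 1.03 in that order and by 0.19 for CO2 in cold-acclimated leaves.

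With 1 array left out the counts ran from 5910 to 8654, 2120 to 3758, 3514 to 4792, 6292 to 8795, 16366 to 18297 and 14885 to 16991. With replicate number as a block they were 8111, 3307, 4492, 8008, 17851 and 16781. The numbers did not pair arrays: 3 of 12 arrays resembled most the array of their own number in another group. Counts under repeated quantile normalisation, median centring, the filter on dim probe sets, cyclic loess, array weights, the trended robust prior and 6-array fits stayed within 1.5 times. Camera tests of the protease and xylanase inhibitor list, and of the combined biotic stress list for CO2, stayed above 0.05 under the alternatives run for them. Median centring, array weights, the trended prior and the removal of cross-hybridising probe sets were not run for lists. The combined list crossed 0.05 for cold at ambient CO2 (0.0329, and 0.0518 after cyclic loess) and at elevated CO2 (0.219, and 0.0345 with all probe sets as background). Correlations of effects moved little without dim probe sets, after cyclic loess and with 1 array left out.

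Of 296 results for named genes, 254 kept direction and call under every setting run for them that used the adjusted p of 0.05 alone. Of the results that were called, 56 missed a 2-fold minimum. Settings that left out probe sets or comparisons did not cover all results. Spike-in rescaling left 113 the same, 7 stronger, 4 weaker and 1 reversed. Without cross-hybridising probe sets 168 were the same and 2 weaker, and without dim probe sets 245 were the same and 3 stronger. The fall of LOC543269 (eIF-2-beta) in the cold at elevated CO2, by 0.33, reversed to 0.21 (adjusted p = 0.0736) after spike-in rescaling. The cause was not tested. Probe sets below the dimmest spike-in control could not be checked against a control of known input, which limits what small changes there can show.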

Other observations

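The relation of the cold-acclimated CO2 effect to the cold effect, and the gene groups below, were chosen only after the values were seen.

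Across probe sets the CO2 effect in cold-acclimated leaves ran against the cold effect averaged over both CO2 levels (r = -0.26), a pair of contrasts that are independent by design. Bias with signal level was examined within 20 bins of mean level over all arrays. The median correlation within bins was -0.1852, with all 20 bins below 0 (-0.354 to -0.0813). These bins cannot exclude such bias, because probe sets of a bin that rose in the cold still had higher levels in the cold-acclimated arrays. A difference between CAEC and CAAC that depends on level would thus still run along the cold effect. The SD across probe sets of an array averaged 2.06 in CAAC and 2.03 in CAEC. Such bias and a partial reversal of the cold response under elevated CO2 both stay open. The relation was found and examined on the same data, and probe sets are not replicates. For the CO2 effect in non-acclimated leaves the pooled r was -0.16. The median within bins was -0.05052 (15 of 20 bins below 0, from -0.354 in the brightest bin to 0.0730). Bias and its absence cannot be told apart here either, since the same bins were used. The 3 brightest bins (-0.244, -0.278 and -0.354) went further than the pooled value, and bins near the floor lay close to 0.

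Among 6 tubulin genes, 4 fell and 1 rose in the cold at each CO2 level. tubb1 (LOC543257), tubb2 (LOC543258), Tubb4 (LOC543260) and Tubb5 (LOC543261) fell by 2.76, 2.52, 0.80 and 1.54 at ambient CO2, and tubb3 (LOC543473) rose by 0.54. As a group they were not called against the other named genes (adjusted p = 0.292 at ambient and 0.130 at elevated CO2, limma's camera, over 6 groups). Of 6 genes of ribosomal proteins and translation factors, 4 rose and 1 fell in the cold at ambient CO2 (adjusted p = 0.292), and 4 rose and 2 fell at elevated CO2 (adjusted p = 0.503). Of 6 genes of electron transport and the Calvin cycle, 1 rose and 3 fell at ambient CO2 (adjusted p = 0.292), and none rose and 2 fell at elevated CO2 (adjusted p = 0.592). The rbcl probe set used (LOC100049018) stood at 13.27 in NAAC, near the top of the scale, where a change would be hard to see.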
